A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

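Gene expression was measured on 12 Affymetrix yeast arrays, 3 for each of 4 groups: BY4741 wild type and a pat1 mutant, each without drug and with 30 µg/ml Congo Red for 2 h. The deposited table holds log2 values made with RMA (background correction, quantile normalization and summary per probe set) per the submitters' processing notes, which give no version. The table had 5739 probe sets with values from 2.33 to 14.32, and no pair of arrays was duplicated. The values were used as deposited, without further scaling. Signal files of single probes were not analysed here. Arrays have no read depth, so the number of arrays limits the precision.

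Of the probe sets, 23 were controls of the array and 218 had no listed gene; both were left out of the gene tests. The other 5498 had 1 symbol each, taken from the platform annotation and brought up to date through the Entrez gene number with the RefSeq gene table of assembly R64, which updated 12 symbols. For 47 genes with more than 1 probe set the brightest was used, which gave 5449 genes tested. Of these, 114 were read by probe sets that may bind related transcripts. The authors' genome build is not given in the sources used here, so no coordinates are given.

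The analysis used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. A model with 4 group means was fitted to all 12 arrays with lmFit and eBayes (8 residual degrees of freedom). The comparisons were Congo Red against no drug in each strain, pat1 against wild type without and with drug, and the difference between the strains in the response to the drug. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are those of the moderated fit.

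Of 31 gene lists written from general knowledge, 30 had measured members. They cover cell wall integrity targets and pathway components, glucan and chitin synthesis, mannoproteins, stress responses, calcineurin targets, mRNA decay, ribosomes, metabolism, metal and phosphate regulons, the cell cycle, mating type, sporulation and strain markers. Each was tested against all other genes with camera at a preset correlation of 0.01, adjusted over 150 tests. Camera with an estimated correlation and the rotation test fry were run beside it. Adjusted over the list alone means that the Benjamini-Hochberg correction ran over the members of a list only. List means are given without taking off the median over all genes. That median was -0.029, 0.041, -0.014, 0.044 and 0.058 in the 5 comparisons, in the order given above, so small list means are to be read against it. The mean response of a list per biological sample was compared between strains with an exact permutation test, whose smallest two-sided p for 3 against 3 is 0.1. Some lists share genes. The mannoprotein list shares PIR3, YPS3, PST1, CWP1, SED1, HSP150 and PIR1 with the cell wall integrity targets. The glucan and chitin list shares GSC2, GFA1, CHS3 and CRH1 with them, and the calcineurin list shares GSC2. The general stress list shares TPS1, TPS2, TSL1, GSY2, PGM2, GPH1 and NTH1 with the trehalose and glycogen list. Calls of lists that share genes thus partly repeat each other.

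The named genes were PAT1, the 10 with the largest change in each direction among those past the threshold with non-overlapping groups (for the difference in response, the 10 largest in each direction whatever their p), the genes of the cell wall integrity targets, and up to 4 members of each list per comparison with the largest absolute change. Genes named outside this rule are said to be chosen after their values were seen. The comparisons, lists, rule and alternative settings were set before the data were examined.

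The series' design text says that each biological sample gave an array without and an array with drug. This was checked on deviations from the group means across genes. Arrays of the same strain and number correlated at 0.648, 0.801 and 0.782 in wild type and at 0.616, 0.732 and 0.668 in pat1. Each correlated best with its own number, the highest other values being -0.019, -0.529, 0.231, -0.201, -0.257 and -0.378, and 0.1 was the bound for pairing. A replicate block by strain and number (4 residual degrees of freedom) was therefore valid for the responses to the drug and was run as an alternative.

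Other alternatives were arrays centred on their medians, quantile and cyclic loess normalization, leaving out the dimmest 25% of genes, eBayes with trend and robust settings, array weights, a limma fit without moderation, only the 2 groups compared, stricter thresholds (adjusted p under 0.01, or at least 2-fold), the mean of all probe sets of a gene, all probe sets, camera on ranks, and each array left out in turn. Chosen after the data were examined were the biological sample as a random block, the data without both arrays with URA3 signal, and the data without wild type sample 2 and pat1 sample 3. The steps were tested on simulated data with independent noise and 200 of 5449 genes changed. That noise left out the pairing of arrays seen here, so the shares recovered are not the power in these data. Of genes changed by log2 1 and 2, 88% and 100% were recovered for the wild type response, 79% and 95% for the strains without drug, and 60% and 93% for the difference in response, with 15 false calls of 203, 8 of 182 and 8 of 161.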

Results

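Transcript levels were measured with 12 Affymetrix yeast arrays in the haploid Saccharomyces cerevisiae strain BY4741 and in a pat1 mutant of it. Pat1 is a protein that binds deadenylated mRNA and takes part in decapping and decay. Congo Red is a dye that binds chitin and glucan and disturbs the assembly of the cell wall. Each strain was grown for 2 h either without drug or with 30 µg/ml Congo Red, and each of the 4 groups had 3 arrays. The array values were log2 signals from 2.33 to 14.32, with medians of 9.53 to 9.70 per array over the 5449 genes tested. The highest median was that of treated pat1 array 3, and the next was 9.60 on treated wild type array 1. Arrays of the same group correlated with Pearson's r of 0.975 to 0.995 across probe sets. The number of arrays limits the precision of every value given here.

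PAT1 itself separated the strains on every array. Its signal lay between 10.50 and 10.93 on the 6 wild type arrays and between 2.95 and 3.94 on the 6 pat1 arrays. The signals of PAT1 differed by -7.26 ± 0.25 (SE, log2, n = 3 arrays per group; limma adjusted p = 2.69e-08) without drug and -7.29 ± 0.25 (limma adjusted p = 2.58e-08) with Congo Red. LEU2 and MET17, both deleted in BY4741, gave signals of 2.95 to 4.2 on all arrays. HIS3, which carries a partial deletion in BY4741, gave 10.53 to 11.18. PAT1 on the pat1 arrays thus lay at the level of deleted genes, and its difference is a lower bound of the loss. URA3, also deleted in this strain, gave 2.94 to 3.27 on 10 arrays, but 7.71 on the second wild type array with Congo Red and 6.76 on the first pat1 array without drug.

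**Figure D1:**
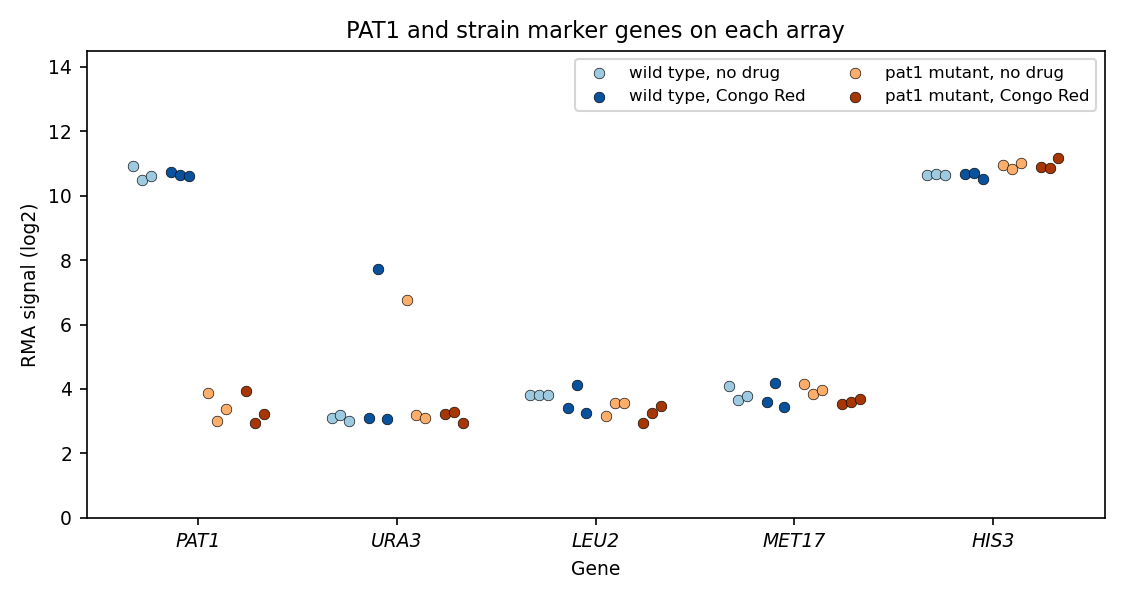
Signal (log2, vertical axis) of PAT1, of 3 genes deleted in BY4741 and of the partly deleted HIS3 on each of the 12 arrays, with 1 point per array and colours for the 4 groups. PAT1 lies between 10.50 and 10.93 on wild type arrays and at or below 3.94 on pat1 arrays, and URA3 stands at 7.71 and 6.76 on 2 arrays only.

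The first comparison asked which transcripts wild type cells change when exposed to Congo Red. Listed targets of the cell wall integrity pathway made up 21 of the 133 genes that rose. PIR3, a structural cell wall protein, rose 24.1-fold (log2 4.59 ± 0.32, SE, n = 3 arrays per group), and KDX1, a kinase related to the pathway's mitogen-activated kinase Slt2, rose 19.1-fold (4.25 ± 0.25). CRG1, a methyltransferase, rose 10.2-fold, the putative aryl alcohol dehydrogenase gene YPL088W 8.83-fold, SRL3 by log2 2.99, and BAG7 by 2.73. YPS3, an aspartic protease anchored at the cell surface, rose by 2.57, AFR1 by 2.3, the uncharacterised gene YJL107C by 2.27, and GSC2, a catalytic subunit of glucan synthase, also by 2.27. Decreases were smaller. SHU2, a member of a DNA repair complex, fell by 1.15, HO, the mating type switching endonuclease gene, fell by 0.84, YDR222W fell by 0.77 and FAL1, an RNA helicase of rRNA maturation, fell by 0.65. IPI3, BMT5 and KRR1, which act in ribosome assembly or rRNA modification, were also among the 10 largest decreases, together with TMA16, RKI1 and THI7.

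In total 146 of 5449 genes passed the limma test in wild type, 133 higher and 13 lower, and 58 of them changed at least 2-fold, 57 higher and 1 lower. In all 146 genes every array of the higher group lay above every array of the lower group. Across all genes 1129 (20.7%) had such non-overlapping groups. Chance gives 10% for independent arrays and less here, since arrays were paired within samples. With the biological sample as a replicate block, 769 genes passed, 448 higher and 321 lower, all 146 among them. The count rested on single arrays: it was 81 without wild type array 1 without drug, 89 without wild type array 3 without drug, and 72 without wild type array 3 with Congo Red.

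Of the 23 measured cell wall integrity targets, 21 rose in wild type, and all 23 rose when adjusted over the list alone or with the replicate block. The exceptions over all genes were MTL1 (1.24, adjusted p = 0.0926) and PIR1 (0.42, adjusted p = 0.0829), with adjusted p = 0.00995 and 0.0163 under the block. SLT2 rose by 1.84, the transcription factor gene RLM1 by 1.30, PRM5 by 2.11, PST1 by 1.68, PTP2 by 1.52, PUN1 by 1.48, CWP1 by 1.46, YPK2 by 1.93, CRH1 by 1.19, DFG5 by 1.18 and the chitin synthase gene CHS3 by 0.92. Among the 21 past the test, SED1 (0.70), SVS1 (0.54) and HSP150 (0.54) rose least. The list mean was 1.77 (camera adjusted p = 2.33e-51, and adjusted p = 0.0164 with an estimated correlation). Among 23 components of the pathway itself, MSG5, a phosphatase acting on Slt2, rose by 1.12 and the sensor MID2 by 0.81, and the list as a whole was not called (mean 0.079, adjusted p = 0.272).

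Genes of glucan and chitin synthesis and remodelling had 9 of 33 members higher, 1 lower and 23 not past the test in wild type, and 17 higher and 1 lower when adjusted over the list alone. GFA1, the first enzyme of chitin precursor synthesis, rose by 1.33 and CHS1 by 1.03. The list mean was 0.46 (adjusted p = 4.68e-14, and adjusted p = 0.0773 with an estimated correlation). Of 23 cell wall mannoproteins 7 rose (10 when adjusted over the list alone), with a mean of 0.55 (adjusted p = 2.64e-06, and adjusted p = 0.199 with an estimated correlation). Among the 7, PIR3, YPS3, PST1, CWP1, SED1 and HSP150 were cell wall integrity targets already counted above. The median of the list was only 0.06, 0.171 and 0.101 in wild type samples 1, 2 and 3. Of 11 calcineurin and Crz1 targets 4 rose (7 adjusted over the list alone). Among them were GSC2 (2.27), a cell wall integrity target already counted above, and YPS1 (1.33). The calmodulin-dependent kinase CMK2 rose by 1.29 and CMP2, a catalytic subunit of calcineurin, by 0.66. The mean of the 11 was 0.62, GSC2 included (adjusted p = 4.27e-08, and adjusted p = 0.025 with an estimated correlation). The unfolded protein response list had a mean of 0.20 (adjusted p = 0.000232, and adjusted p = 0.0374 with an estimated correlation), although none of its 20 members passed alone and 5 rose with the block. SIL1, at 0.56, had the largest value in it.

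Of 61 ribosome biogenesis genes only KRR1, which fell by 0.55, passed over all genes and over the list alone in wild type, and 31 fell with the block. The list mean was -0.36 (adjusted p = 1.56e-16, and adjusted p = 0.464 with an estimated correlation). The 129 cytosolic ribosomal protein genes had a mean of -0.085 with no member past the test (adjusted p = 0.000728, and adjusted p = 0.569 with an estimated correlation). In the osmotic stress and glycerol list only HAL1, a halotolerance gene, rose among 15 members (2.03), 5 rose with the block, and the mean was 0.32 (adjusted p = 0.00174, and adjusted p = 0.0773 with an estimated correlation). In the sulfur assimilation list no gene passed over all genes and 3 of 21 did when adjusted over the list alone (mean 0.25, adjusted p = 0.00285, and adjusted p = 0.519 with an estimated correlation). Histone genes had a mean of -0.20 (adjusted p = 0.00568, and adjusted p = 0.522 with an estimated correlation). Values in brackets after an array are list means without it, given where the call was lost or the mean moved over 1.5 times. The ribosomal protein list lost its call without treated wild type array 3 (-0.051). The sulfur list lost its call without untreated wild type array 2 (0.12), and kept it without treated wild type array 1 (0.15) or 2 (0.40). The histone list lost its call without untreated wild type array 2 (-0.15).

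The general stress list had a mean of 0.17 in wild type (adjusted p = 0.0263, and adjusted p = 0.843 with an estimated correlation), with NTH1, the neutral trehalase, as its only riser (0.79). The second wild type array with Congo Red and its untreated partner carried general stress genes 0.38 and 0.59 above their group means. The trehalose and glycogen list (mean 0.17, adjusted p = 0.0465, and adjusted p = 0.752 with an estimated correlation) and the respiration list (mean 0.11, adjusted p = 0.0445, and adjusted p = 0.843 with an estimated correlation) had 1 riser each, NTH1 and the citrate synthase gene CIT1 (0.72). Means of 0.09 for the proteasome (adjusted p = 0.0181, and adjusted p = 0.623 with an estimated correlation), -0.092 for mRNA deadenylation, decapping and decay (adjusted p = 0.0338, and adjusted p = 0.464 with an estimated correlation) and 0.19 for sporulation genes (adjusted p = 0.0382, and adjusted p = 0.464 with an estimated correlation) completed the 16 called lists. The sporulation call was lost with the block (adjusted p = 0.0861). The block added calls for glucose-repressed genes (mean 0.15, adjusted p = 0.0669 without and 0.0106 with the block) and the iron regulon (mean -0.19, adjusted p = 0.0775 without and 0.0152 with the block). The general stress list lost its call without untreated wild type array 1 (0.028) or 3 (0.009), treated wild type array 2 (-0.024) or both URA3-positive arrays (-0.024), and kept it without untreated wild type array 2 (0.46) or treated wild type array 1 (0.27). The trehalose list lost its call without untreated wild type array 1 (0.080) or 3 (0.033), treated wild type array 2 (0.026), treated pat1 array 1 (adjusted p = 0.0506) or 2 (adjusted p = 0.0525) or both URA3-positive arrays (0.026), and kept it without untreated wild type array 2 (0.39). The respiration list lost its call without untreated wild type array 1 (0.083) or 3 (0.020), treated wild type array 2 (0.017), treated pat1 array 2 (adjusted p = 0.0525) or both URA3-positive arrays (0.017), and kept it without untreated wild type array 2 (0.22) or treated wild type array 3 (0.17). The proteasome list lost its call without untreated wild type array 2 (0.044) or treated wild type array 1 (0.064) or 3 (0.054), and kept it without treated wild type array 2 (0.15). The mRNA decay list lost its call without untreated wild type array 1 (-0.094) or 3 (-0.074) or treated wild type array 3 (-0.085). The sporulation list lost its call without untreated wild type array 1 (0.14) or 3 (0.19), treated wild type array 2 (0.19), untreated pat1 array 1 (adjusted p = 0.0503) or both URA3-positive arrays (0.19).

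**Figure D2:**
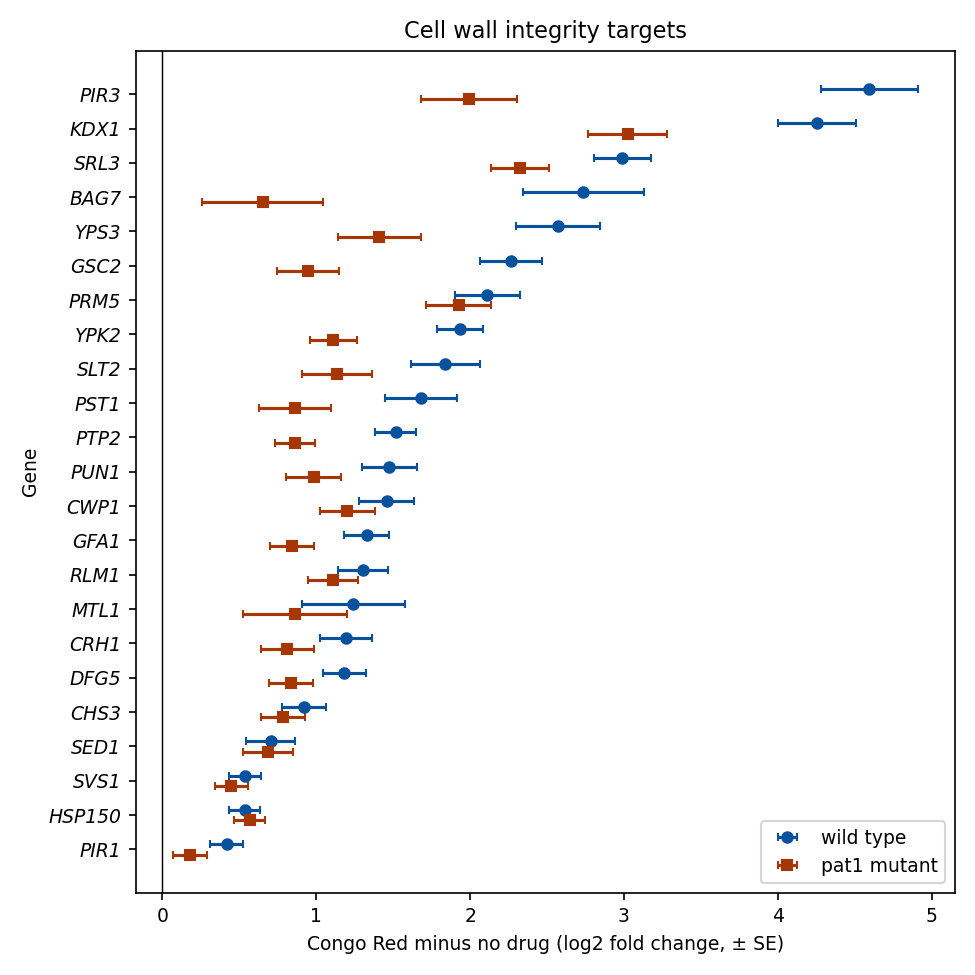
Log2 fold change of Congo Red over no drug (horizontal axis, mean ± SE of the limma fit, n = 3 arrays per group) for each of the 23 measured cell wall integrity targets, in wild type (circles) and in the pat1 mutant (squares). PIR3 reaches 4.59 in wild type and 1.99 in pat1, and HSP150 is the only gene with the higher value in pat1 (0.57 against 0.54).

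The second comparison gave the response of the pat1 mutant to the same dose. KDX1 rose 8.13-fold (log2 3.02 ± 0.25, SE, n = 3 arrays per group), SRL3 5.01-fold (2.33 ± 0.19), CRG1 4.27-fold and PIR3 3.98-fold. PRM5 rose by 1.93, AFR1 by 1.65, PHO89, a sodium-dependent phosphate transporter, by 1.52, YPS3 by 1.41 (adjusted p = 0.0426), YNL058C by 1.27 and HAL1 by 1.23. IME2, a kinase of meiosis, rose by 0.88 in the mutant and by 0.77 in wild type.

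In pat1, 36 genes passed, all of them higher and all with non-overlapping groups, and 14 rose at least 2-fold. Non-overlapping groups occurred in 8.15% of all genes. The 10% that chance gives for independent arrays is too high a reference here, since arrays were paired within samples. With the replicate block 957 genes had an unadjusted limma p under 0.05, where chance gives 272. With the replicate block 126 genes passed, 107 higher and 19 lower, all 36 among them. The count fell to 13 without the first pat1 array with Congo Red, to 21 without the second, and to 18 and 19 without pat1 array 2 or 3 without drug, to 11 with the 6 arrays of these 2 groups alone, and to 12 without wild type sample 2 and pat1 sample 3.

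Of the 23 cell wall integrity targets 14 rose in pat1, 21 when adjusted over the list alone and 19 with the block, with a mean of 1.11 (adjusted p = 4.7e-50, and adjusted p = 0.0164 with an estimated correlation). YPK2 rose by 1.11, CWP1 by 1.20, RLM1 by 1.11, PUN1 by 0.98, PTP2 by 0.86, GFA1 by 0.84, DFG5 by 0.84, CHS3 by 0.78 and HSP150 by 0.57. SLT2 (1.14), GSC2 (0.95), PST1 (0.86), CRH1 (0.81) and SED1 (0.68) passed over all genes only with the block, at adjusted p = 0.00324, 0.024, 0.00118, 0.0165 and 0.0204. BAG7 (0.65), MTL1 (0.86), SVS1 (0.45) and PIR1 (0.18) did not pass over all genes in either fit, and of the 9 only BAG7 and PIR1 did not pass over the list alone. Glucan and chitin genes had 5 of 33 members higher, 12 adjusted over the list alone, among them PCM1 of the chitin precursor pathway (0.94), and a mean of 0.32 (adjusted p = 2.79e-11, and adjusted p = 0.128 with an estimated correlation). Of 11 calcineurin targets 3 rose (8 adjusted over the list alone), with a mean of 0.52 (adjusted p = 1.35e-10, and adjusted p = 0.0164 with an estimated correlation). Of 23 mannoproteins 5 rose (8 adjusted over the list alone), with a mean of 0.29 (adjusted p = 1.73e-05, and adjusted p = 0.236 with an estimated correlation).

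No member of the other lists called in pat1 passed over all genes. The unfolded protein response list had a mean of 0.16 (adjusted p = 0.00168, and adjusted p = 0.072 with an estimated correlation), heat shock genes -0.17 (adjusted p = 0.000164, and adjusted p = 0.409 with an estimated correlation), the iron regulon -0.17 (adjusted p = 0.000331, and adjusted p = 0.224 with an estimated correlation) and histones -0.13 (adjusted p = 0.000423, and adjusted p = 0.464 with an estimated correlation). General stress genes had a mean of -0.20 (adjusted p = 0.000771, and adjusted p = 0.664 with an estimated correlation). Ribosome biogenesis had -0.067 (adjusted p = 0.000166, and adjusted p = 0.737 with an estimated correlation). Cytosolic ribosomal proteins had -0.051 (adjusted p = 9.2e-07, and adjusted p = 0.464 with an estimated correlation). Oxidative stress genes had -0.049 (adjusted p = 0.0424, and adjusted p = 0.464 with an estimated correlation). In this comparison the median over all genes was 0.041. The auxotrophic markers had -0.45, led by URA3 at -1.21 (adjusted p = 0.0394, and adjusted p = 0.509 with an estimated correlation), and lost the call with the block (adjusted p = 0.0872). The block added calls for respiration (mean -0.03, adjusted p = 0.0508 without and 0.0141 with the block) and the mating pheromone response (mean 0.15, adjusted p = 0.095 without and 0.0218 with the block). The general stress list lost its call without untreated pat1 array 3 (0.099) or treated pat1 array 1 (-0.035) or 2 (-0.070), and kept it without untreated pat1 array 1 (-0.36) or 2 (-0.34) or treated pat1 array 3 (-0.50). The heat shock list lost its call without untreated pat1 array 1 (-0.043), treated pat1 array 3 (-0.13) or both URA3-positive arrays (-0.043). The unfolded protein list lost its call without treated pat1 array 1 (0.14). The ribosome biogenesis list lost its call without untreated pat1 array 2 (0.055) or treated pat1 array 3 (-0.042), and kept it without untreated pat1 array 3 (-0.17) or treated pat1 array 1 (-0.011) or 2 (-0.15). The iron list lost its call without untreated pat1 array 1 (-0.067), treated pat1 array 3 (-0.11) or both URA3-positive arrays (-0.067), and kept it without untreated pat1 array 3 (-0.30). The histone list kept its call without untreated pat1 array 3 (-0.084) or treated pat1 array 1 (-0.073). The oxidative stress list lost its call without untreated pat1 array 1 (0.010), treated pat1 array 2 (-0.035) or 3 (-0.072), both URA3-positive arrays (0.010) or wild type sample 2 and pat1 sample 3 (-0.10), and kept it without untreated pat1 array 2 (-0.078) or 3 (-0.080). The auxotrophic marker list lost its call without untreated pat1 array 1 (-0.16) or 3 (-0.58) or treated pat1 array 1 (-0.40) or 2 (-0.45).

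Next, the mutant was set against wild type without drug. Apart from PAT1, the largest decreases among genes past the threshold included phosphate genes, Ty element genes and HXT1. PHO5, the secreted acid phosphatase, was 9.5-fold lower in pat1 (log2 -3.25 ± 0.51, SE, n = 3 arrays per group), PHM6 4.10-fold lower (-2.03 ± 0.32), PHO89 3.80-fold lower (-1.93 ± 0.14) and PHO11, another acid phosphatase, 2.89-fold lower. HXT1, a low-affinity glucose transporter, was 4.34-fold lower. The Ty element genes YBL100W-A, YBL005W-A, YAR009C and YBL100W-B were 6.25-fold, 4.25-fold, 2.55-fold and 2.48-fold lower, each on a probe set shared between copies, so that no single copy can be named. Higher in pat1 were the catalase gene CTT1 (1.92), CLD1, a cardiolipin deacylase (1.78), FMP45 (1.73), SPO22, a meiosis gene (1.68), the drug transporter QDR2 (1.61), the chitin deacetylase CDA1 (1.58), SPG4 (1.55), GSC2 (1.54), FRE5 (1.45) and YEL073C (1.44).

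In this comparison 351 genes passed, 191 higher and 160 lower, all with non-overlapping groups, but only 24 with the 6 arrays of these 2 groups alone, and 58 differed at least 2-fold, 39 higher and 19 lower. The balance of directions was not stable: 136 were higher and 173 lower with the dimmest 25% of genes left out, and 119 higher and 165 lower without moderation. Non-overlapping groups made up 26.9% of all genes, where chance gives 10%. The other 6 arrays of the fit came from the same biological samples and were treated as independent. With the sample as a random block 287 genes passed. The count was 58, 199 and 73 without wild type array 1, 2 or 3 without drug, 118 and 86 without pat1 array 1 or 3 without drug, and 200 and 233 without wild type array 1 or 3 with Congo Red, which adds only to the estimate of spread. Without wild type sample 2 and pat1 sample 3, a choice made after the data were examined, 169 genes passed, 113 higher and 56 lower, and without both arrays carrying URA3 signal 89 passed.

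Of the 13 measured genes of the phosphate regulon, 8 were lower and 1 higher in pat1 without drug, and 9 were lower and 1 higher when adjusted over the list alone. PHO8, the vacuolar alkaline phosphatase, was lower by log2 -1.17, and GIT1, a glycerophosphoinositol transporter, was higher by 0.88, both named after their values were seen. The list mean was -0.93 (adjusted p = 1.83e-07, and adjusted p = 0.0289 with an estimated correlation). With Congo Red, 7 were lower and 1 higher (9 and 1 adjusted over the list alone), with a mean of -0.75 (adjusted p = 1.83e-07, and adjusted p = 0.0289 with an estimated correlation). There PHO5 was 6.66-fold lower, PHM6 3.29-fold lower, PHO11 by log2 -1.38, PHO8 by -0.94 and PHO89 by -0.84.

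**Figure D3:**
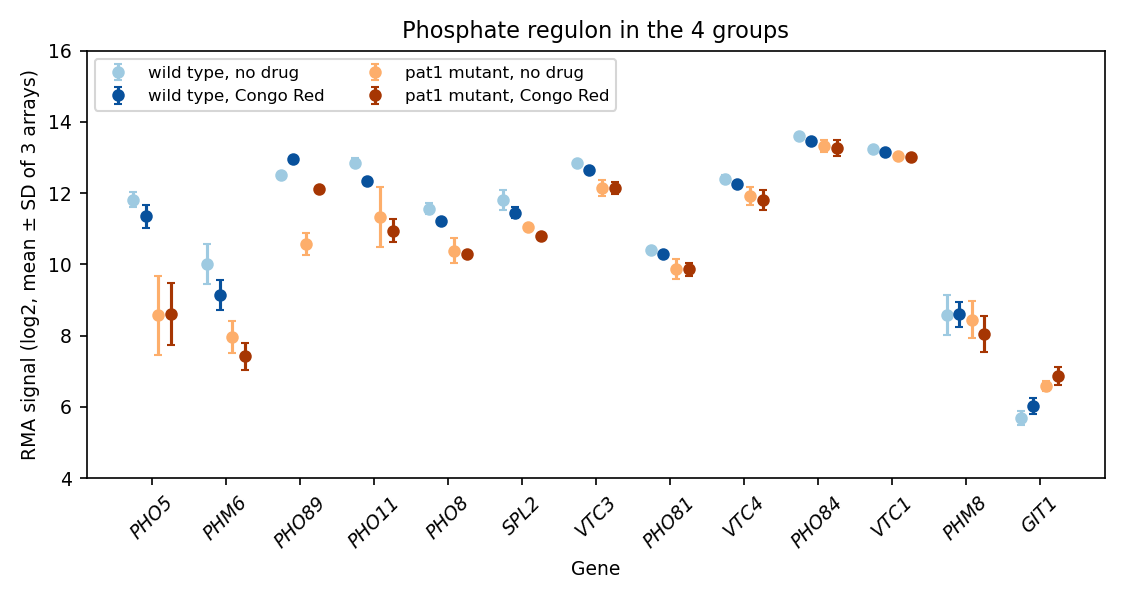
Signal (log2, mean ± SD of 3 arrays, vertical axis) of the 13 measured phosphate regulon genes in the 4 groups, given by colour. PHO5, PHM6, PHO89, PHO11 and PHO8 lie lower in both pat1 groups than in both wild type groups, and GIT1 lies higher.

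Of 44 respiration genes 5 were higher in pat1 without drug over all genes and 5 over the list alone, among them CYT1 (1.39), QCR7 (1.11) and COR1 (0.82), all subunits of complex III. The list mean was 0.38 (adjusted p = 2.64e-06, and adjusted p = 0.567 with an estimated correlation). General stress genes had 3 of 32 members higher, 7 adjusted over the list alone, with CTT1 the largest (1.92), and a mean of 0.75 (adjusted p = 1.34e-05, and adjusted p = 0.569 with an estimated correlation). HSP12 (2.46, adjusted p = 0.163), SOL4 (1.86, adjusted p = 0.0793) and HSP26 (1.82, adjusted p = 0.157) had high values but did not pass. Of 20 trehalose and glycogen genes, the glycogen branching enzyme GLC3 (1.38) and the glycogen synthase GSY1 (1.35) were higher, with a list mean of 0.48 (adjusted p = 0.0066, and adjusted p = 0.623 with an estimated correlation). These 3 lists also varied between cultures: on wild type sample 2 and pat1 sample 3 general stress genes lay 0.38 to 0.60 above their group means on all 4 arrays. Without those 2 samples the general stress mean was 0.74, the trehalose mean 0.52 and the respiration mean 0.33. This leaves out 1 sample of each strain, so it cannot test them as a source. The strains overlapped without drug. General stress genes had a mean of 9.86 on wild type array 2, and 9.698 and 9.741 on pat1 arrays 1 and 2 (exact two-sided permutation p = 0.3). Trehalose genes had 9.842 on that wild type array, and 9.651 and 9.708 on those pat1 arrays. The respiration list kept its call without untreated pat1 array 3 (0.22). The general stress list kept its call without untreated pat1 array 3 (0.45). The trehalose list lost its call without untreated wild type array 3 (0.34) or untreated pat1 array 3 (0.29).

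Iron regulon genes had 2 of 18 members higher without drug, FIT2 (1.06) and HMX1 (0.59), and a mean of 0.30 (adjusted p = 0.00361, and adjusted p = 0.408 with an estimated correlation). In the list of G2 and M phase genes MYO1 was lower by log2 -0.68, 4 of 13 were lower adjusted over the list alone, and the mean was -0.24 (adjusted p = 0.00877, and adjusted p = 0.519 with an estimated correlation). Pathway components of cell wall integrity had 1 member higher and 2 lower, including BEM2 (-0.43), and a mean of -0.15 (adjusted p = 0.0335, and adjusted p = 0.199 with an estimated correlation). Cytosolic ribosomal proteins had a mean of -0.099 (adjusted p = 0.000771, and adjusted p = 0.569 with an estimated correlation) and glucose-repressed genes a mean of 0.26 (adjusted p = 0.043, and adjusted p = 0.509 with an estimated correlation), with no member past the test in either. Among the 38 genes of mRNA deadenylation, decapping and decay, LSM3 was higher (0.94), CDC39, the scaffold of the Ccr4-Not complex, was lower (-0.79) and SKI3 was lower (-0.69), and the list was not called (mean -0.073, adjusted p = 0.14). The cell wall integrity targets had 1 of 23 members higher, GSC2, with a mean of 0.041 and a median of -0.065 (adjusted p = 0.892). The iron list lost its call without untreated pat1 array 1 (0.19) or both URA3-positive arrays (0.19). The G2 and M phase list lost its call without both URA3-positive arrays (-0.14), and kept it without untreated pat1 array 1 (-0.14). The pathway component list lost its call without untreated wild type array 1 (-0.14), untreated pat1 array 3 (-0.14) or wild type sample 2 and pat1 sample 3 (-0.15). The ribosomal protein list lost its call without wild type sample 2 and pat1 sample 3 (-0.054). The glucose-repressed list lost its call without untreated wild type array 3 (0.18) or untreated pat1 array 3 (0.16).

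A further comparison set the strains against each other under Congo Red. Beside the phosphate genes, the decreases included PIR3, 3.35-fold lower in pat1 (log2 -1.74 ± 0.32, SE, n = 3 arrays per group), and YPL088W, 4.37-fold lower (-2.13 ± 0.29). HXT1 was 3.98-fold lower, SPO11, the meiotic recombination endonuclease, 3.17-fold lower, YPR078C 2.82-fold lower, and the Ty genes YBL100W-A and YBL005W-A 5.67-fold and 3.34-fold lower. SPO22 was higher by 1.66, the putative permease SEO1 by 1.53, the glutathione exchanger GEX1 by 1.5, YJL218W by 1.49, CLD1 by 1.41, CDA1 by 1.40, QDR2 by 1.40, YEL073C by 1.35, DSF1 by 1.33 and SHU2 by 1.29. GEX1 and DSF1 were read by probe sets shared with near copies.

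Under Congo Red 351 genes passed, 232 higher and 119 lower (210 with the 6 arrays of these 2 groups alone), and 47 differed at least 2-fold, 25 higher and 22 lower. Here too the other 6 arrays came from the same biological samples, and 290 genes passed with the sample as a random block. All 351 had non-overlapping groups, as had 29.7% of all genes, where chance gives 10%. The share higher was 66.1%, but 51.4% with arrays centred on their medians, 52.3% after quantile normalization and 47.5% after cyclic loess. With array weights 445 were higher and 375 lower, and without both URA3-positive arrays 106 and 90. The count was 145, 152 and 92 without wild type array 1, 2 or 3 with Congo Red, 199 and 125 without pat1 array 2 or 3 with Congo Red, 202 without wild type array 1 without drug, 113 without wild type sample 2 and pat1 sample 3, and 196 without both URA3-positive arrays.

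Of the 23 cell wall integrity targets 8 were lower in pat1 under Congo Red and 15 when adjusted over the list alone, with a mean of -0.62 (adjusted p = 2.62e-11, and adjusted p = 0.18 with an estimated correlation). Beside PIR3 these were KDX1 (-1.23), YPS3 (-1.16), SRL3 (-0.83), GFA1 (-0.79), PTP2 (-0.73), YPK2 (-0.64) and CHS3 (-0.55). Glucan and chitin genes had 6 of 33 members lower and 1 higher (10 and 1 adjusted over the list alone), including the exoglucanase EXG2 (-1.01) and the glucan synthase homologue FKS3 (0.71), and a mean of -0.20 (adjusted p = 0.000245, and adjusted p = 0.464 with an estimated correlation). MSG5 was lower (-0.74) and PKH1 higher (0.45) among the pathway components, whose mean was -0.13 (adjusted p = 0.021, and adjusted p = 0.178 with an estimated correlation). Ribosome biogenesis had 5 of 61 members higher, among them SPB1 (0.80), NOP7 (0.68) and KRR1 (0.61), and a mean of 0.19 (adjusted p = 0.00479, and adjusted p = 0.843 with an estimated correlation). The iron regulon had 4 of 18 members higher, among them FIT2 (0.91) and the siderophore transporters ARN1 (0.69) and SIT1 (0.65), and a mean of 0.31 (adjusted p = 0.0234, and adjusted p = 0.464 with an estimated correlation). The ribosome biogenesis list lost its call without treated wild type array 2 (0.10), treated pat1 array 2 (0.11) or both URA3-positive arrays (0.10), and kept it without treated wild type array 1 (0.30). The iron list lost its call without treated wild type array 1 (0.33) or treated pat1 array 1 (0.27) or 2 (0.29).

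Smaller list shifts under Congo Red were -0.15 for heat shock genes (adjusted p = 0.0087, and adjusted p = 0.519 with an estimated correlation), -0.14 for the unfolded protein response (adjusted p = 0.0201, and adjusted p = 0.178 with an estimated correlation) and -0.23 for daughter cell separation (adjusted p = 0.0201, and adjusted p = 0.54 with an estimated correlation). G2 and M phase genes had -0.13, with ALK1 lower (-0.47; adjusted p = 0.0382, and adjusted p = 0.569 with an estimated correlation), sulfur assimilation -0.12 (adjusted p = 0.043, and adjusted p = 0.623 with an estimated correlation) and ribosomal proteins -0.065, with RPL15B lower (-0.47; adjusted p = 0.000771, and adjusted p = 0.569 with an estimated correlation). In the mRNA decay list LSM3 was higher (1.16) and CDC39 (-0.55) and the exonuclease gene XRN1 (-0.47) were lower, with a list mean of 0.021 and a median of -0.003 (adjusted p = 0.583). Among G1 to S genes RAD27, a flap endonuclease, was higher (1.00) and so was the DNA ligase CDC9 (0.55), and the list was not called (mean 0.091, adjusted p = 0.483). The heat shock list lost its call without treated pat1 array 3 (-0.11) or wild type sample 2 and pat1 sample 3 (-0.12). The unfolded protein list lost its call without treated pat1 array 3 (-0.11) or wild type sample 2 and pat1 sample 3 (-0.12). The daughter cell separation list lost its call without treated wild type array 3 (-0.13) or treated pat1 array 1 (-0.14). The G2 and M phase list lost its call without treated wild type array 1 (-0.091) or 3 (-0.11) or treated pat1 array 1 (-0.037). The sulfur list lost its call without untreated wild type array 3 (adjusted p = 0.0529), treated wild type array 1 (-0.020) or 3 (-0.070), untreated pat1 array 1 (adjusted p = 0.0503) or treated pat1 array 3 (-0.089), and kept it without treated wild type array 2 (-0.26). The ribosomal protein list lost its call without treated wild type array 2 (-0.036), both URA3-positive arrays (-0.036) or wild type sample 2 and pat1 sample 3 (-0.026), and kept it without treated wild type array 3 (-0.099).

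The last comparison asked whether the response to Congo Red differed between the strains. At the level of gene lists, the cell wall integrity targets had the smaller mean response in pat1. Their mean response was 1.77 ± 0.17 in wild type and 1.11 ± 0.25 in pat1 (SD, n = 3 biological samples per strain), so that the mutant reached 62.7% of the wild type value on the log2 scale. Each wild type sample lay above each pat1 sample, and an exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 samples allow. The separation was not particular to this list. Glucan and chitin, mannoprotein, general stress, osmotic, respiration, glucose-repressed and proteasome genes had the same p and direction. Ribosome biogenesis and mRNA decay genes had the same p in the other direction. The list mean of the difference was -0.66 (camera adjusted p = 4.01e-24, and adjusted p = 0.0423 with an estimated correlation). The largest negative differences among the targets were PIR3 (-2.60), BAG7 (-2.08), GSC2 (-1.32), KDX1 (-1.23) and YPS3 (-1.16), while PRM5 (-0.18), SVS1 (-0.089) and SED1 (-0.019) differed little and HSP150 had a difference of 0.033. GSC2 was 1.54 higher in untreated pat1 cells and 0.22 higher under Congo Red (not past the test), so its smaller response came with a higher start. PIR3 and BAG7 also lay higher in untreated pat1 cells, by 0.86 and 0.71, without passing (adjusted p = 0.123 and 0.299).

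**Figure D4:**
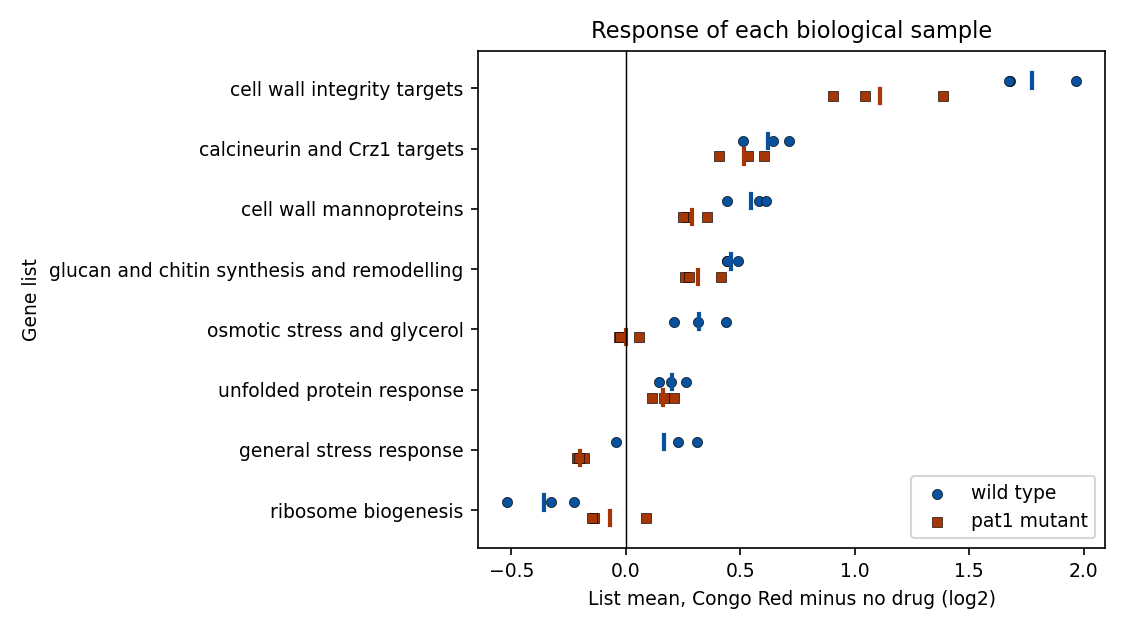
Mean response to Congo Red (log2, horizontal axis) over the members of 8 gene lists, with 1 point for each of 3 wild type (circles) and 3 pat1 (squares) biological samples and a bar at each strain's mean. For the cell wall integrity targets the strain means are 1.77 and 1.11, and for osmotic stress and glycerol 0.32 and 0.001.

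The osmotic stress and glycerol list also had a smaller mean response in pat1 (-0.32, adjusted p = 1.8e-06, and adjusted p = 0.0224 with an estimated correlation), with RTC3 at -1.25, HAL1 at -0.79 and GPP2 at -0.77. Further lists called with a negative difference were general stress (-0.37, adjusted p = 5.44e-09, and adjusted p = 0.509 with an estimated correlation), mannoproteins (-0.26, adjusted p = 0.000978, and adjusted p = 0.464 with an estimated correlation) and trehalose and glycogen (-0.23, adjusted p = 0.000408, and adjusted p = 0.54 with an estimated correlation). Glucose-repressed genes had -0.19 (adjusted p = 0.000388, and adjusted p = 0.224 with an estimated correlation), sulfur assimilation -0.17 (adjusted p = 0.000487, and adjusted p = 0.464 with an estimated correlation) and glucan and chitin genes -0.14 (adjusted p = 2.51e-05, and adjusted p = 0.409 with an estimated correlation). The mannoprotein and the glucan and chitin lists share PIR3 and GSC2, among others, with the cell wall integrity targets. The general stress and the trehalose lists share genes with each other, NTH1 among them. Respiration had -0.14 (adjusted p = 3.18e-05, and adjusted p = 0.59 with an estimated correlation). Sporulation genes had -0.12 (adjusted p = 0.0423, and adjusted p = 0.478 with an estimated correlation; adjusted p = 0.0806 with the block) and the proteasome -0.052 (adjusted p = 0.00497, and adjusted p = 0.569 with an estimated correlation). Ribosome biogenesis was the only called list with a positive difference (0.29, adjusted p = 5.39e-11, and adjusted p = 0.54 with an estimated correlation). For this difference the median over all genes was 0.058. With the block and an estimated correlation together no list was called in any comparison, with adjusted p = 0.283 for the osmotic list and 0.293 for the cell wall integrity targets here. The rotation test fry gave adjusted p = 0.0591 for the cell wall integrity targets and 0.0424 for the osmotic list. The glucan and chitin list kept its call without treated wild type array 3 (-0.080). The mannoprotein list lost its call without untreated wild type array 2 (-0.19) or wild type sample 2 and pat1 sample 3 (-0.27). The general stress list kept its call without untreated wild type array 1 (-0.23), 2 (-0.66) or 3 (-0.21), treated wild type array 2 (-0.18), untreated pat1 array 3 (-0.066) or treated pat1 array 1 (-0.20), 2 (-0.24) or 3 (-0.66). The trehalose list lost its call without untreated pat1 array 3 (-0.043), and kept it without untreated wild type array 1 (-0.14), 2 (-0.46) or 3 (-0.095), treated wild type array 2 (-0.088) or treated pat1 array 2 (-0.13) or 3 (-0.40). The ribosome biogenesis list kept its call without untreated pat1 array 3 (0.19). The respiration list lost its call without untreated pat1 array 3 (0.016) or treated pat1 array 1 (-0.003), and kept it without untreated wild type array 2 (-0.25) or 3 (-0.050), treated wild type array 2 (-0.047), untreated pat1 array 1 (-0.28) or treated pat1 array 3 (-0.28). The sulfur list lost its call without untreated wild type array 2 (-0.042), and kept it without untreated wild type array 1 (-0.26), treated wild type array 1 (-0.071) or 2 (-0.32) or untreated pat1 array 1 (-0.088) or 3 (-0.28). The glucose-repressed list kept its call without untreated wild type array 3 (-0.10), treated wild type array 2 (-0.10) or untreated pat1 array 3 (-0.088). The proteasome list lost its call without untreated wild type array 2 (-0.006), treated wild type array 3 (-0.016), untreated pat1 array 2 (-0.008) or treated pat1 array 3 (-0.052), and kept it without untreated wild type array 3 (-0.085), treated wild type array 1 (-0.026) or 2 (-0.11), untreated pat1 array 1 (-0.086) or treated pat1 array 1 (-0.024) or 2 (-0.081). The sporulation list lost its call without untreated wild type array 1 (-0.066) or 3 (-0.11), treated wild type array 2 (-0.12) or 3 (-0.10), untreated pat1 array 3 (-0.029), treated pat1 array 1 (-0.10) or 2 (-0.053) or wild type sample 2 and pat1 sample 3 (-0.17), and kept it without treated pat1 array 3 (-0.20).

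No single gene passed for the difference in response with limma. At an unadjusted p under 0.05 there were 130 genes in this fit, which ignores the pairing of arrays within biological samples, and 659 with the replicate block, where chance gives 272. The smallest adjusted p was 0.429 without the block. PIR3 had this value at a difference of -2.60, so the absence of genes past the test does not show that large differences are absent. A limma fit with array weights gave 1 gene. A random block, chosen after the data were examined, gave 11, of which 1 responded more in pat1, PHO89 (adjusted p = 0.0156), and 10 less: PIR3 (0.0278), YPL088W (0.0278), MCH5 (0.0278), FLC1 (0.0278), BAG7 (0.0337), GSC2 (0.0364), PRB1 (0.0364), YNR065C (0.0364), HAL1 (0.0387) and YPK2 (0.0438), with MCH5, FLC1 and PRB1 named after their values were seen. PHO89 lay lower in pat1 both without drug and under Congo Red, as given above, so its larger response came with a lower start. Without pat1 array 1 without drug 1 gene passed, and without pat1 array 1 with Congo Red 3 did. With the replicate block 3 genes passed, all responding less in pat1: YJL107C (-1.26, adjusted p = 0.0199), YNR065C (-1.45, adjusted p = 0.043) and PRM10 (-1.002, adjusted p = 0.0353), the last named after its values were seen. The replicate block and the random block had 1 gene in common, YNR065C, while YJL107C and PRM10 had adjusted p = 0.106 and 0.124 there, and all 3 had adjusted p = 1 without a block. Adjusted over the list alone, 7 of the 23 cell wall integrity targets passed, and 12 with the block. The largest positive differences were PHO89 (1.09, adjusted p = 0.429, and 0.0505 with the replicate block), APE1 (1.01), GUP2 (0.86), YBR196C-A (0.85) and FAF1 (0.80), and the other large negative ones YPL088W (-2.11), YNR065C, YJL107C and CRG1 (-1.26). URA3 had the most negative value (-2.72 ± 1.64, SE), from the 2 arrays with URA3 signal.

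Set against each other across genes, which are not independent replicates, the 2 responses correlated with Pearson's r of 0.684. They share no arrays. Of the 36 genes that rose in pat1, 34 also rose in wild type, where independent lists would share 0.879. The other 2 were PHO89 (1.52 in pat1, 0.44 in wild type with adjusted p = 0.165, and 0.0234 with the block) and GPI18, a mannosyltransferase of GPI anchor synthesis (0.59 in pat1, 0.32 in wild type with adjusted p = 0.252), the latter named after its values were seen. All 133 genes that rose in wild type had positive values in pat1, and 131 of them were smaller there. Because those genes were chosen in wild type, the 50 most induced genes were also picked in 2 wild type samples and read in the sample left out. The median was 1.48, 1.45 and 1.92 in the wild type samples left out, and 0.785 to 1.01 in the pat1 samples. Picked in 2 pat1 samples instead, the 50 genes had medians of 0.804 to 0.959 in the pat1 sample left out and 1.26 to 1.56 in the wild type samples.

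Other lists served as checks of the cells. Genes specific to mating type alpha had means of 0.033 (median -0.029), -0.041, 0.40 and 0.32 in the 4 comparisons of groups, none called, and only STE3, the receptor of alpha cells, passed, without drug (1.26). Every pat1 array nevertheless had a higher mean of this list than every wild type array, 5.70 to 5.91 against 5.36 to 5.48 without drug and 5.67 to 5.87 against 5.37 to 5.49 with Congo Red. Sporulation genes were called in the wild type response alone among those comparisons, with SPO11 (1.47) and IME2 (0.77) as the 2 genes that rose, and without drug IME2 was higher (0.80) and ZIP1 lower (-0.91) in pat1. Amino acid biosynthesis genes (means -0.079, -0.035, 0.037 and 0.081) and ergosterol genes (-0.025, 0.038, -0.138 and -0.075) were called in none of the 5 comparisons. None of the 8 mitochondrially encoded genes listed was measured.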

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

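The tests of explanations in this part, the counts over other splits of the samples included, were chosen after the results were seen, while the comparison of the strains' responses was planned.

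For 12 gene lists a camera test of the difference between the strains in the response to Congo Red passed its threshold. The mean differences, pat1 minus wild type on the log2 scale, were -0.662 for cell wall integrity targets, -0.367 for general stress, -0.321 for osmotic stress and glycerol, -0.255 for mannoproteins, -0.231 for trehalose and glycogen, -0.187 for glucose-repressed genes, -0.169 for sulfur assimilation, -0.141 for glucan and chitin genes, -0.138 for respiration, -0.119 for sporulation genes, -0.052 for the proteasome and 0.289 for ribosome biogenesis. With an estimated correlation only the cell wall integrity targets and the osmotic list stayed past the threshold, and with the block as well no list did. The mannoprotein list and the glucan and chitin list share genes with the cell wall integrity targets and are not separate findings. The general stress list and the trehalose list also share genes, NTH1 among them, and are not separate findings either. Samples of the 2 strains overlapped for trehalose, sulfur and sporulation (exact permutation p = 0.2 each), and mannoproteins, trehalose, respiration, sulfur, the proteasome and sporulation, 6 of the 12, lost their call without some single array, respiration at 0.016 without pat1 array 3 without drug. With the replicate block 3 single genes differed, YJL107C (-1.261), PRM10 (-1.002) and YNR065C (-1.452), and in each of them all 3 wild type samples responded more than all 3 pat1 samples. Of these only YNR065C also passed with the random block, and none passed without a block (adjusted p = 1 each).

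The weaker response of the cell wall integrity targets in pat1 was set against 3 explanations. A higher starting level in untreated pat1 cells would need a list mean near the size of the difference, but that mean was 0.041 ± 0.055, although GSC2 started 1.54 higher and PIR3 and BAG7 lay 0.86 and 0.71 higher without passing, so for these 3 genes a part from the start stays open. Scaling between arrays left the difference at -0.677 or further from 0 under 3 other scalings. For a smaller response of drug-induced genes at large, 50 induced genes outside the cell wall lists were read. The pat1 median was the smaller in 9 of 9 pairs of samples with genes picked in wild type, and in 9 of 9 with genes picked in pat1. The pairs reuse 3 samples per strain and are not independent trials. Only listed genes were left out, so unlisted genes of the same pathway may remain. The values therefore cannot tell a weaker output of the pathway from a weaker response at large. The weaker response may be part of a weaker reaction of many induced genes, but this was not shown for all. The unfolded protein response list (0.20 and 0.16, exact permutation p = 0.5) had overlapping samples. So had the calcineurin targets (0.62 and 0.52, exact permutation p = 0.3). Of these 11, PHO89 rose more in pat1 (1.52 against 0.44 in wild type), from a lower start. GSC2, also a cell wall integrity target, rose less in pat1 (0.95 against 2.27). These 2 genes move the list mean in opposite directions. The mean without them was not computed, so the overlap does not settle the response of the other members. Dye uptake, growth and mRNA turnover in pat1 were not tested.

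URA3, deleted in BY4741, gave a signal of 6.76 on the first pat1 array without drug and 7.71 on the second wild type array with Congo Red. RNA of PAT1-carrying cells on that pat1 array would raise PAT1, but PAT1 there stood at -0.07 relative to the highest other pat1 array. For a defect of the arrays, 0 other genes showed such a gap on this pair of arrays, but HSP30 (2.28) and DAN1 (2.29) stood out on the pat1 array alone, whose array weight was the lowest (0.339). This leaves a defect of the arrays open, and it and real URA3 RNA cannot be told apart with 1 probe set. No biological explanation was tested.

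General stress genes had a mean 0.747 higher in untreated pat1 cells. Leaving out the 2 biological samples that stood apart gave 0.739. Without drug these samples, 1 in each strain, lay 0.586 and 0.601 above their group means on this list. Leaving out both lowers the means of both strains alike, so this cannot test them as a source. Spread between biological samples stays open, since an exact two-sided permutation test over the 6 arrays gave p = 0.3. A difference between the strains also stays open.

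Among the 218 probe sets without a listed gene, which no comparison used, 11 were higher with Congo Red in wild type and 2 in pat1. Between the strains 7 were higher and 5 lower in pat1 without drug, and 8 higher and 7 lower with Congo Red. Their transcripts were not identified.

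The 6 arrays of each comparison of groups can be split 3 against 3 in 10 ways, too few for a share under 0.05. For the difference in response the 6 biological samples were split instead. In the other splits of arrays any real effect lies within the sides and adds to the spread. Low counts there thus say little. In the wild type response 1 of 10 splits, the real one, reached 146 genes, and the highest other gave 0. In the pat1 response 1 of 10 reached 36, and the highest other gave 1. For the strains without drug and with Congo Red 1 of 10 reached 351 in each, and the highest other gave 0. For the difference in response all 10 of 10 gave 0 genes. Of the splits of the drug responses, 4 part all 3 pairs of arrays, the real one among them, and the other 3 of these gave 0 genes in both strains.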

How the results depend on the processing

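The random block, the data without both arrays with URA3 signal, and the data without wild type sample 2 and pat1 sample 3 were alternatives chosen after the results were seen; the rest were planned.

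The difference in PAT1 stayed past the threshold in every setting run, between -7.486 and -7.058 without drug and between -7.577 and -7.083 with Congo Red when 1 array was left out. With the dimmest 25% of genes left out PAT1 itself was removed, so that setting gives no value. Over the named genes and the alternatives, 3456 results kept direction and side of the threshold, 874 no longer passed and 0 reversed. Over the called gene lists these numbers were 1001, 167 and 8. Of the main counts and values, 148 stayed near the first value and 56 moved. For a count of 351, for example, 256 was taken as near and 233 as moved. For the correlation of 0.684 between the responses, 0.631 was taken as near and 0.608 as moved. The cause was not tested unless stated.

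In the wild type response to Congo Red, 146 genes (133 higher, 13 lower) became 717 with array weights (484 and 233), 830 with a random block (462 and 368), 58 at 2-fold or more and 72 at an adjusted p under 0.01. Leaving out 1 array gave 72 to 161. With the replicate block, by which each biological sample pairs its 2 arrays, the count was 769.

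In the pat1 response, 36 genes became 22 with cyclic loess, 23 without moderation, 11 with only the 2 groups compared (fewer arrays for the spread), 168 with a random block, 12 without wild type sample 2 and pat1 sample 3, 14 at 2-fold or more and 13 at an adjusted p under 0.01. Leaving out 1 array gave 13 to 39. With the replicate block it was 126. In the 2 responses the block kept all 146 and all 36 genes, and it ended the list calls of sporulation genes in wild type (adjusted p = 0.0861), of auxotrophic markers in pat1 (0.0872) and of sporulation genes in the difference between responses (0.0806).

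Between the strains without drug, 351 genes became 889 with array weights, 24 with only the 2 groups compared, 89 without both arrays with URA3 signal, 169 without wild type sample 2 and pat1 sample 3, 58 at 2-fold or more and 46 at an adjusted p under 0.01. Leaving out 1 array gave 58 to 363. With Congo Red, 351 became 820, 210, 196, 113, 47 and 67 in the same order, and 92 to 446 with 1 array left out. Across the strains the replicate numbers did not pair: deviations of arrays with the same number correlated at 0.264, -0.547 and -0.439 without drug and at -0.083, -0.417 and -0.229 with Congo Red. A block by number gave 349 and 368 genes, of which 289 and 307 were shared with the 351.

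For the difference in response, 0 genes became 1 with array weights, 11 with a random block and 3 with the replicate block, and 0 to 3 with 1 array left out. The correlation of the 2 responses across genes, 0.684, was 0.493 to 0.739 with 1 array left out and 0.809 over genes changed at least 2-fold in wild type, which are chosen for size.

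Means of 6 called list results, from 5 lists, changed sign. General stress in wild type with Congo Red was -0.0235 without both arrays with URA3 signal, and -0.0235 to 0.4584 with 1 array left out. In the pat1 response general stress ranged from -0.499 to 0.0993, ribosome biogenesis from -0.1694 to 0.0549, and oxidative stress from -0.0803 to 0.0103 with 1 array left out, the last also reaching 0.0103 without both arrays with URA3 signal. The auxotrophic markers were 0.0264 with dim genes left out, where fewer members remain, and -0.6037 to -0.1572 with 1 array left out. Respiration in the difference between responses ranged from -0.2808 to 0.0164. With an estimated correlation 53 list results no longer passed.

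Median centring ended the calls of auxotrophic markers in pat1 (adjusted p = 0.0622), glucose-repressed genes between untreated strains (0.0512), sulfur assimilation between treated strains (0.0677) and sporulation in the difference (0.0622). Leaving out the dimmest 25% of genes ended 10 list calls beside that of the auxotrophic markers: trehalose (0.0656), mRNA decay (0.0937) and sulfur (0.0889) in wild type, oxidative stress in pat1 (0.0937), pathway components (0.0669) and glucose-repressed genes (0.26) between untreated strains, sulfur (0.0633) and G2 and M phase genes (0.104) between treated strains, and sulfur (0.131) and glucose-repressed genes (0.196) in the difference. The 2 sporulation calls had no value there. Camera on ranks ended those of mannoproteins (0.0633) and sporulation (0.0671) in the difference.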

Other observations

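The reading of wild type sample 2 and pat1 sample 3 as standing apart was chosen after the data were seen.

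Within groups, the first principal component of the deviations from group means held 45.1% of the variance. Wild type sample 2 scored 17.28 without drug and 12.2 with Congo Red, and pat1 sample 3 scored 15.48 and 12.38, while the other 8 arrays lay between -10.43 and -5.34. Both arrays of each sample had the same sign.

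Among the neighbours of PAT1 on its chromosome, chosen after their values were seen, PTC6 was higher in pat1 without drug (0.58, adjusted p = 0.0319) and had a value of 0.47 with Congo Red (adjusted p = 0.0613). FUB1 (0.48 and 0.42), EGO2 (-0.38 and -0.49) and SRB8 (-0.37 and -0.24) did not pass in either comparison.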
